A study of Homo sapiens with 12 samples.

How the data were processed

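Total RNA from HuCCT1 and Huh28, established human cholangiocarcinoma cell lines, was measured on 12 Agilent one-colour arrays, each hybridised with Cy3-labelled RNA. The labels describe overnight serum starvation, then 1 ng/mL recombinant human TGFβ for 16 h or no TGFβ, in triplicate, which gives 4 groups of 3 arrays. HuCCT1 was grown in RPMI-1640 and Huh28 in MEM, per the labels' protocols. The labels do not say whether the replicates of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

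The deposited scanner files hold spot intensity on a linear scale, background-subtracted and detrended by Agilent Feature Extraction 10.7.1.1 per the file headers (10.7.3.1 per the submitters' processing notes). No scaling between arrays is recorded in these files. The deposited value table holds log2 values of 35014 probes. Each of its columns correlated at r = 0.9998 or more with the matching array's log2 signal after scaling to the 75th percentile and subtracting each probe's median, over 24349 bright probes, and at most at 0.9813 with any other array. The slopes on that signal were 0.9994 to 1.001, and the median of each probe in the table lay within 5e-07 of 0. The values thus fit log2 signal centred on each probe's median, while the filter and the floor of the table stayed unknown. The column medians lay between -0.169 and 0.177, and were, for replicates 1, 2 and 3, 0.103, 0.153 and 0.158 in the HuCCT1 controls, 0.177, 0.158 and 0.146 in treated HuCCT1, -0.149, -0.156 and -0.169 in the Huh28 controls and -0.109, -0.14 and -0.145 in treated Huh28. It served as an alternative.

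Each array had 61657 spots other than controls. Of 50683 distinct probes, 28174 were named through their transcript accession in the RefSeq gene table of GRCh38.p14 (20503 symbols), and 22509 matched nothing there and kept the accession or probe name of the files. The array design was annotated on hg19 per the file headers, another build than that table, so no coordinates are given. Genes with a near-identical copy (CGB3 and LHB, AKR1B10 and AKR1B15, CTAG1A) can share signal between probes, and their identity is uncertain. The lncRNA class was set from the accession and symbol, and a gene is called noncoding in that sense.

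Spots with an outlier mark were left out (408 to 599 per array), replicate spots were averaged, and the signal was divided by the array's 75th percentile, multiplied by 1000, raised to a floor of 20 and taken as log2. The floor (4.32 on the log2 scale) was set after the signal distribution had been looked at and before any test. A probe was tested when it was well above background on all 3 arrays of at least 1 group, and a gene was represented by its probe with the highest mean level, which left 28094 genes (17055 under a gene symbol, 5012 noncoding). Among 5229 genes with several such probes, 41 in HuCCT1 and 5 in Huh28 had probes past the threshold in opposite directions. Values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and 8 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. A gene is said to rise, fall or change where it passed that threshold, and changes are treated minus control on the log2 scale, with the fitted standard error (SE). The SE pools the 4 groups, and arrays at the floor show no spread. For genes at the floor in a group the SE and p can therefore be too small. Where a gene was not well above background on any array of one group, its fold is given as "at least", from the brighter group's mean against the lowest signal well above background in the dimmer group, as means of normalised log2 values. The 5 contrasts were TGFβ in each line, the mean over the lines, the difference between lines (Huh28 minus HuCCT1) and the untreated lines against each other. The R package data.table (version 1.17.8) was used and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

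The 27 gene lists (616 genes, 564 tested) were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and adjusted over the lists of a contrast. The lists, the design, the named genes and most alternatives were chosen before the data were examined. Named were the 10 largest rises and 10 largest falls per contrast among genes past the threshold with a symbol, whose 3 treated and 3 control arrays did not overlap (not asked of the difference), 14 fixed genes, up to 4 members of each list with the smallest p, the 10 largest mean rises and falls among genes called in both lines, and 3 noncoding genes each way. A few genes that these rules name are not reported here. The fit was tested on simulated data of 28050 genes, with 50 genes changed per fold size. For HuCCT1 it recovered 34% of genes changed 1.25-fold, 68% at 1.5-fold, 92% at 2-fold and 96% at 4-fold, and called 15 of 27850 unchanged genes. For Huh28 the shares were 28%, 60%, 84% and 88%, with 11 of 27850 unchanged genes called. The shifted list was called in each simulation and none of the 26 others was. Far fewer genes were changed in the simulation than were called in the real data. The adjusted threshold was therefore stricter there, and the recovery shares need not hold for the real fit. The simulated noise was independent between genes, so this does not show how the list test behaves where genes are correlated. In the real data the estimated correlation reached 0.197, in the cell cycle list.

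Alternatives were normexp background correction (offset 50), quantile normalisation, the percentile over bright probes, no filter or a stricter one (well above background on all 12 arrays), keeping marked spots, averaging a gene's probes, testing each probe, a fit with the replicate number as a block, separate fits per line, eBayes with trend and robust estimation, a 2-fold minimum, a threshold of 0.01, the deposited value table, other list tests (fry) and leaving out each array. Scaling on spike-in controls and floors of 5 and 50 were added after the data had been seen. Normexp used the median signal and names came from accessions, in place of the mean-signal and gene-name columns foreseen in the design, which were not used here. Replicate arrays of a group correlated at r = 0.9932 to 0.9982 over genes, and no pair held identical values.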

Results

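Gene expression was profiled in HuCCT1 and Huh28, established lines of cholangiocarcinoma, a cancer of the bile duct epithelium, with and without transforming growth factor beta (TGFβ), a cytokine that signals through SMAD transcription factors. The series set out to describe the TGFβ signature of these lines. Serum-starved cells received 1 ng/mL TGFβ for 16 h or none, with 3 arrays in each of 4 groups, and 28094 genes were tested. The 75th percentile of the signal lay between 882 and 1225 over the 12 arrays, 33485 to 42523 spots per array were well above background, and no spot was saturated. The number of arrays limits the precision. The HuCCT1 control replicate 1 had the highest number of spots at or below 0 after background subtraction (13157, against 5337 to 11012 on the other arrays) and the fewest well above background.

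Each line was hybridised on its own slide, with controls in the upper row and treated samples in the lower one. Each line also had its own culture medium. Line, slide and medium thus cannot be told apart, and neither can treatment and row. All contrasts of TGFβ within a line are within a slide. The lowest signal well above background was 17.2 to 35.0 on control arrays and 12.9 to 14.4 on treated arrays. Across genes the first principal component held 92.9% of the variance and separated the lines. Levels are given on the log2 scale with the 75th percentile of each array set to 1000. On that scale the 7 brighter spike-in controls, RNAs added in fixed amounts, were lower on treated arrays by a median log2 difference of -0.156 in HuCCT1 (-0.227 to -0.0808) and -0.115 in Huh28 (-0.171 to -0.0975). Scaling on them raised treated arrays against controls by 0.158 (SE 0.215) in HuCCT1 and 0.129 (SE 0.38) in Huh28, which moved the median change of all genes to 0.154 and 0.103, so changes below are relative to the 75th percentile.

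In HuCCT1, TGFβ raised 22 of 30 TGFβ/SMAD target genes and lowered ID1, ID2 and ID3. IL11, a secreted cytokine of the interleukin-6 family, went from a log2 level of 8.45 ± 0.13 (SD, n = 3) to 12.58 ± 0.07, a 17.4-fold rise (log2 change 4.12, SE 0.07, adjusted p = 6.03e-11). ID1, an inhibitor of helix-loop-helix transcription factors and a target of BMP signalling, fell from 14.83 ± 0.05 to 11.59 ± 0.05, or 9.43-fold (log2 change -3.24, SE 0.05, adjusted p = 4.68e-11), and ID3, of the same family, fell by 2.64 (SE 0.06). The largest rise was that of FOXS1, a forkhead transcription factor, at 5.15 (SE 0.17), although it was well above background on only 1 of 3 control arrays. FOXS1 lost this rank with normexp correction (3.30) and with a floor of 50 (4.24), since CGB3 stayed at 4.417 or more in every setting. In all, 4228 genes were higher and 4073 lower, 29.5% of those tested, and 494 and 233 of them by at least 2-fold.

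**Figure D1:**
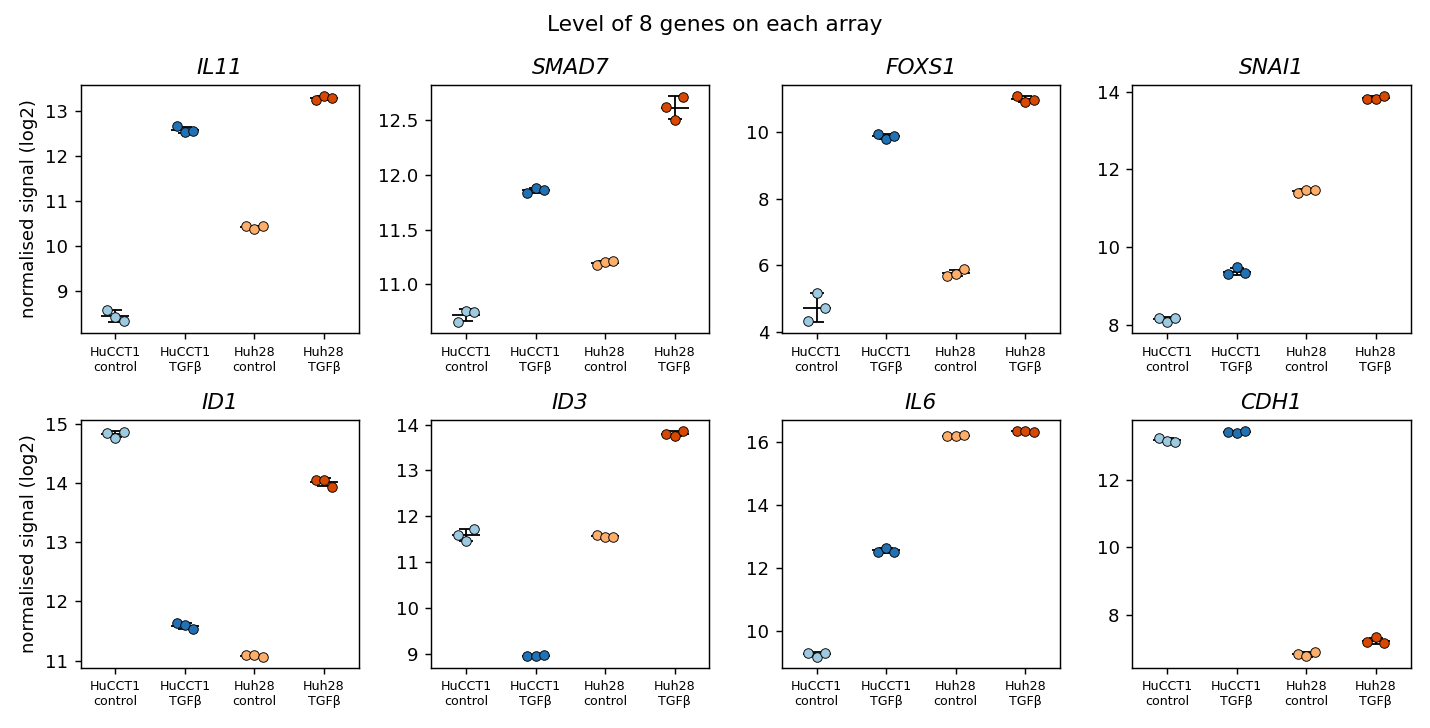
Normalised signal (log2, 75th percentile of each array at 1000) of 8 genes on each of the 12 arrays, by line and treatment, with points for arrays and bars for the mean and SD of 3 arrays. ID1 fell from 14.83 to 11.59 in HuCCT1 and rose from 11.09 to 14.02 in Huh28, while IL11, SMAD7, FOXS1 and SNAI1 rose in both lines.

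The other large rises in HuCCT1 were in CGB3 (4.67, SE 0.07) and LHB (4.35, SE 0.08), which encode beta subunits of gonadotropins and are near-identical in sequence. ODAPH (4.53, SE 0.06), which encodes a phosphoprotein of tooth enamel, and GPA33 (4.40, SE 0.03), a surface antigen of intestinal epithelium, followed. The difference of GPA33 between the lines had the same size (-4.40), which leaves no change in Huh28. Its SE may thus be held down by the floor. Then came ANGPTL4 (4.28, SE 0.06), an inhibitor of lipoprotein lipase, and the metalloprotease ADAM19 (3.97, SE 0.05). XYLT1, which starts glycosaminoglycan chains, was not well above background in controls and was at least 15.4-fold higher with TGFβ (adjusted p = 4.67e-11). After ID1, the largest falls were in PPFIBP2 (-3.05, SE 0.08, well above background on 1 of 3 treated arrays), SPRY1 (-2.98, SE 0.25), an inhibitor of receptor tyrosine kinase signalling, and EVI2B (-2.71, SE 0.14). PPFIBP2 lost this rank with normexp correction (-1.555) and with a floor of 50 (-1.734), since ID3 stayed at -2.444 or lower in every setting. Further falls were in FLG (-2.51, SE 0.06), which encodes the skin protein filaggrin, PRR15L (-2.49, SE 0.06), the aldo-keto reductases AKR1B10 (-2.44, SE 0.16) and AKR1B15 (-2.43, SE 0.07), and LRP2 (-2.27, SE 0.15), the endocytic receptor megalin. By the rule that chose these genes, the 3 treated arrays lay on one side of the 3 controls in each.

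Of 30 TGFβ/SMAD target genes, 22 rose and 1 fell in HuCCT1 (23 and 1 adjusted over the list alone). Among them were SMAD7 (1.13, SE 0.05) and SKIL (1.63, SE 0.09), which restrain the pathway. PMEPA1 (0.81, SE 0.05), CCN2 (1.99, SE 0.07), a matricellular protein, and the integrin subunit ITGB6 (2.58, SE 0.04) also rose. The list shifted upwards against other genes (camera, adjusted p = 7.89e-16). Mesenchymal genes of the epithelial-mesenchymal transition followed, with 15 of 25 higher and 3 lower (16 and 3 adjusted over the list alone, camera adjusted p = 1.15e-06). The transcription factors SNAI1 (1.23, SE 0.05), SNAI2 (1.18, SE 0.09) and ZEB1 (1.48, SE 0.08) rose, as did vimentin, VIM (0.71, SE 0.08). WNT5B and ITGB3 were not well above background in controls and were at least 9.29-fold (adjusted p = 4.22e-11) and 4.11-fold (adjusted p = 2.87e-09) higher with TGFβ. Epithelial junction and splicing genes moved both ways, with 9 higher and 11 lower of 29 (9 and 12 adjusted over the list alone, camera adjusted p = 0.270). The epithelial transcription factor ELF3 (-2.05, SE 0.07) and the tight junction gene CLDN1 (-1.58, SE 0.07) fell, plakoglobin, JUP, rose (1.06, SE 0.05), and E-cadherin, CDH1, was slightly higher (0.24, SE 0.06, adjusted p = 0.0104).

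Lists of adhesion, matrix and contractility genes shifted upwards in HuCCT1. Among integrins and adhesion genes, 18 of 22 rose and 1 fell (also 18 and 1 adjusted over the list alone, camera adjusted p = 1.52e-08). ITGA2 rose by 1.86 (SE 0.07) and ITGAV by 0.91 (SE 0.04). Of 30 matrix remodelling genes 18 rose and 4 fell (19 and 4 adjusted over the list alone, camera adjusted p = 2.83e-07). The urokinase gene PLAU was at 2.20 (SE 0.04) and the collagen cross-linking enzyme LOX at 1.82 (SE 0.04). Of 25 actin and contractility genes 17 rose and 3 fell (19 and 3 adjusted over the list alone, camera adjusted p = 6.16e-08). Tropomyosin TPM1 was at 1.91 (SE 0.04) and TAGLN at 1.64 (SE 0.08). Extracellular matrix genes had 14 of 30 higher and 4 lower (14 and 4 adjusted over the list alone), led by COL1A1 (2.92, SE 0.05) and SPOCK1 (2.24, SE 0.05). Their camera test gave adjusted p = 0.000161 and adjusted p = 0.0570 with an estimated correlation. ER stress genes, with 11 of 20 higher and 3 lower (12 and 3 adjusted over the list alone, camera adjusted p = 0.000161), included the chaperone HSPA5 (1.49, SE 0.04), HERPUD1 (1.38, SE 0.05) and XBP1 (0.84, SE 0.05). Inflammatory cytokines were mixed, with 13 of 29 higher and 6 lower (13 and 6 adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.215 with an estimated correlation). IL6 (3.29, SE 0.05), IL1A (2.71, SE 0.05) and IL1B (1.64, SE 0.04) rose, and the neutrophil chemokine CXCL8 fell (-0.32, SE 0.05).

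Falling groups in HuCCT1 were led by cell cycle and DNA replication genes, of which 26 of 32 fell and 1 rose (27 and 2 adjusted over the list alone, camera adjusted p = 1.31e-11, adjusted p = 0.0524 with an estimated correlation). The list median was -0.311, with falls in E2F2 (-1.10, SE 0.05), MCM2 (-0.59, SE 0.06) and MCM3 (-0.50, SE 0.04), the last 2 of the replicative helicase. With spike-in scaling 0 of them passed the threshold and the list median was -0.153. Among NRF2-linked and detoxification genes 14 of 22 fell and 0 rose (15 and 1 adjusted over the list alone, camera adjusted p = 8.22e-07). CYP1B1 (-1.53, SE 0.07) and ALDH3A1 (-1.59, SE 0.12) were among them. Sterol and fatty acid synthesis genes had 12 of 22 lower and 0 higher (13 and 0 adjusted over the list alone, camera adjusted p = 2.68e-05, adjusted p = 0.0883 with an estimated correlation). The elongase ELOVL6 was at -0.90 (SE 0.05). Interferon response genes had 12 of 29 lower and 2 higher (14 and 2 adjusted over the list alone, camera adjusted p = 0.000422, adjusted p = 0.106 with an estimated correlation). They were led by IFIT2 (-1.47, SE 0.05) and IFIT1 (-1.30, SE 0.12). In the BMP/ID list 8 of 20 fell and 4 rose (8 and 4 adjusted over the list alone, camera adjusted p = 0.0373, adjusted p = 0.119 with an estimated correlation). ID2 (-1.65, SE 0.05) and the activin antagonist follistatin, FST (-1.77, SE 0.06), fell. The list's call ended without control replicate 2 (adjusted p = 0.0544), without treated replicate 1 (0.0569) and with the replicate number as a block (0.091).

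The remaining 14 lists did not pass the camera test in HuCCT1, the epithelial one included. Members that rose and fell were 11 and 7 of 23 YAP/TEAD targets (adjusted p = 0.0582), and 10 and 5 of 22 WNT and NOTCH genes (0.0582). They were 4 and 1 of 13 stem cell genes (0.0956) and 9 and 5 of 25 TGFβ ligands, receptors and activators (0.189). For hypoxia and glycolysis they were 7 and 2 of 22 (0.189), and for mesothelial and other lineage markers 4 and 2 of 10 (0.189). NF-kB genes had 6 and 7 of 15 (0.243) and EGFR/MAPK genes 9 and 11 of 24 (0.288). Leukocyte and endothelial markers had 3 and 2 of 14 (0.355), fibroblast markers 2 and 1 of 14 (0.466) and hepatocyte markers 1 and 0 of 9 (0.466). Biliary lineage genes had 5 and 5 of 24 (0.865) and long noncoding RNAs 8 and 6 of 23 (0.985), whose mean (0.112) and median (-0.0505) differed in sign. Adjusted over the list alone these counts were 12 and 7 for YAP/TEAD targets, 11 and 7 for TGFβ ligands, 8 and 2 for hypoxia and 8 and 8 for long noncoding RNAs, and did not move for the others. Without control replicate 1 the YAP/TEAD (0.0371) and the WNT and NOTCH list (0.0398) passed. Among markers of other cell types, CSF1R, the receptor of the macrophage growth factor CSF1, rose by 2.91 (SE 0.07), the basal keratin KRT14 by 2.94 (SE 0.08), and the monocyte antigen CD14 fell by 1.22 (SE 0.05). Single members of other lists that changed were VEGFA (1.76, SE 0.07), DUSP1 (1.63, SE 0.03), TNFAIP2 (-1.87, SE 0.03) and the NOTCH ligand JAG1 (1.46, SE 0.06).

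Of the 13 lists past the threshold in HuCCT1, 7 held with an estimated correlation: TGFβ/SMAD targets, mesenchymal genes, matrix remodelling, actin, integrins, NRF2 and ER stress. Another split of the same 6 arrays gave up to 8 lists past the preset-correlation threshold, and 0 with an estimated correlation. Each such split still held more treated arrays on one side, so it kept part of the TGFβ difference. The TGFβ/SMAD list was called in 9 of these 9 splits with the preset correlation. Without control replicate 1, which stood apart in background, 7628 genes passed (48.6% higher). The count of 8301 changed genes dropped to 611 with spike-in scaling, of which 80.0% were higher against 50.9%, and 67 of 115 named and called results kept their call. ID1, ID3 and the largest changes above were all among those kept. PMEPA1 (0.97, SE 0.32), VIM (0.87, SE 0.31), CDH1 (0.40, SE 0.30) and CXCL8 (-0.16, SE 0.30) no longer passed. The median SE of all genes was 0.307 with that scaling against 0.0817, and of these 4 changes only that of CXCL8 was smaller than without it. FLG did not pass with the deposited value table (adjusted p = 0.103), nor did CDH1 with normexp correction (0.0616). Among the changes that normexp correction made smaller by over 1.5 times in fold were those of FOXS1 (3.30), GPA33 (3.19), PPFIBP2 (-1.55), EVI2B (-2.06), FLG (-1.70) and PRR15L (-1.40). A floor of 50 did so for changes that included FOXS1 (4.24) and PPFIBP2 (-1.73), a floor of 5 for FLG (-0.85), and the mean of a gene's probes for FLG (-1.74) and KRT14 (2.13). The bounds given for XYLT1, WNT5B and ITGB3 hold for the main setting only, since the log2 changes were 2.47, 1.94 and 0.97 with normexp correction and 2.90, 2.17 and 0.99 with a floor of 50, below these bounds. When tested genes were divided by level into 4 classes of like size, 73.9% of the calls in the dimmest class were rises, against 43.8% in the brightest.

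In Huh28, TGFβ raised 25 of 30 TGFβ/SMAD target genes and, unlike in HuCCT1, raised ID1 and ID3. ID1 rose from a log2 level of 11.09 ± 0.02 (SD, n = 3) to 14.02 ± 0.07, or 7.64-fold (log2 change 2.93, SE 0.05, adjusted p = 1.56e-09), and ID3 by 2.24 (SE 0.06, adjusted p = 1.23e-08). FOXS1 again had the largest rise, at 5.22 (SE 0.17, adjusted p = 3.51e-08), here well above background on all control arrays. In all, 2556 genes were higher and 2378 lower, 17.6% of those tested, with 229 and 130 of them at least 2-fold. The largest fall was that of the potassium channel KCNJ2 (-2.60, SE 0.25). KCNJ2 lost this rank with normexp correction (-1.70), since EVI2A stayed at -2.003 or lower in every setting.

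The other large rises in Huh28 were in CSF1R (3.42, SE 0.07), PROC (3.16, SE 0.12), the anticoagulant protein C, and ODAPH (3.05, SE 0.06). They were followed by NKAIN4 (2.91, SE 0.07), IL11 (2.86, SE 0.07), the homeobox gene PRRX2 (2.80, SE 0.12), MDFI (2.71, SE 0.10), an inhibitor of myogenic transcription factors, and RPRML (2.66, SE 0.07). The other large falls were in SGPP2 (-2.42, SE 0.11), a sphingosine phosphate phosphatase, the metallothionein MT1F (-2.32, SE 0.61, adjusted p = 0.0247) and LRRN4CL (-2.25, SE 0.13). EVI2B (-2.24, SE 0.14) and EVI2A (-2.16, SE 0.05) fell, as did the transcription factor HLF (-2.22, SE 0.08), the cytokine IL24 (-2.06, SE 0.12), OSR1 (-2.00, SE 0.11), another transcription factor, and the potassium channel KCNA4 (-2.00, SE 0.14).

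Of 30 TGFβ/SMAD target genes, 25 rose and 0 fell in Huh28 (25 and 1 adjusted over the list alone, camera adjusted p = 1.99e-22). Among them were PMEPA1 (2.50, SE 0.05), SMAD7 (1.42, SE 0.05), SKIL (1.24, SE 0.09), CCN2 (1.15, SE 0.07) and TGFBI (1.38, SE 0.05). Of 25 mesenchymal genes 8 rose and 2 fell (13 and 3 adjusted over the list alone, camera adjusted p = 0.00246). SNAI1 rose by 2.38 (SE 0.05) and S100A4 fell by 0.53 (SE 0.05), whereas SNAI2 (0.05, SE 0.09, adjusted p = 0.865), ZEB1 (-0.05, SE 0.08, adjusted p = 0.832) and VIM (0.24, SE 0.08, adjusted p = 0.0864) did not pass. Epithelial genes had 5 of 29 higher and 4 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.874), and CDH1 rose slightly (0.40, SE 0.06, adjusted p = 0.000775).

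The lists of matrix and of actin genes shifted upwards against other genes in Huh28 too. Extracellular matrix genes had 16 of 30 higher and 4 lower (16 and 4 adjusted over the list alone, camera adjusted p = 3.12e-05). Tenascin TNC was at 2.03 (SE 0.16), COL7A1 at 0.93 (SE 0.06) and versican VCAN at 0.72 (SE 0.05). Matrix remodelling genes had 14 of 30 higher and 3 lower (16 and 3 adjusted over the list alone, camera adjusted p = 2.56e-05). ADAM19 (0.98, SE 0.05) and PLAU (0.90, SE 0.04) rose. Actin and contractility genes had 12 of 25 higher and 0 lower (21 and 0 adjusted over the list alone, camera adjusted p = 6.69e-10), including TPM1 (1.06, SE 0.04) and ACTN1 (0.45, SE 0.06). In the BMP/ID list 11 of 20 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.45e-06). BMP6 was at 1.70 (SE 0.16) and BMP4 at -0.91 (SE 0.07). Biliary lineage genes had 11 of 24 higher and 1 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.000264). The keratins KRT7 (0.81, SE 0.06) and KRT18 (0.66, SE 0.04) and the receptor FGFR2 (0.90, SE 0.07) rose. Cell cycle genes had 7 of 32 higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.000755, adjusted p = 0.365 with an estimated correlation). CCND1 was at 0.88 (SE 0.05) and CCNA2 at 0.67 (SE 0.05).

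The other 18 lists did not pass in Huh28. Members that rose and fell were 2 and 7 of 29 interferon response genes (adjusted p = 0.0503), 7 and 5 of 23 YAP/TEAD targets (0.129) and 9 and 3 of 25 TGFβ ligands, receptors and activators (0.129). At an adjusted p of 0.222 they were 6 and 4 of 22 integrins, 3 and 6 of 22 NRF2 genes, 5 and 2 of 14 fibroblast markers and 6 and 2 of 23 long noncoding RNAs. At 0.257 they were 5 and 2 of 15 NF-kB genes, 6 and 4 of 22 hypoxia genes and 6 and 2 of 20 ER stress genes. EGFR/MAPK genes had 7 and 4 of 24 (0.276), WNT and NOTCH genes 9 and 5 of 22 (0.276), hepatocyte markers 0 and 1 of 9 (0.284) and leukocyte and endothelial markers 3 and 2 of 14 (0.375). Inflammatory genes had 9 and 8 of 29 (0.859) and mesothelial and other lineage markers 1 and 1 of 10 (0.859). Sterol and fatty acid genes had 4 and 4 of 22 (0.860) and stem cell genes 2 and 2 of 13 (0.986). Mean and median differed in sign in the last 2 of these. The interferon list passed without single arrays, with an adjusted p down to 0.0183 without treated replicate 3 of Huh28. Adjusted over the list alone the counts were 4 and 7 for interferon, 10 and 3 for TGFβ ligands, 7 and 4 for integrins, 3 and 7 for NRF2 and 7 and 2 for NF-kB. They were 7 and 5 for EGFR/MAPK, 3 and 3 for leukocyte, 10 and 8 for inflammatory, 1 and 2 for mesothelial and 5 and 4 for sterol genes, and did not move for the others. IFIT1 (-1.50, SE 0.12), the chemokines CXCL2 (-1.41, SE 0.06) and CXCL8 (-0.82, SE 0.05), PTGS2 (-1.08, SE 0.06), the integrin ITGB8 (-1.65, SE 0.05) and the WNT inhibitor DKK1 (-1.08, SE 0.06) fell. IL6 was bright in Huh28 without TGFβ (16.20 ± 0.02, SD, n = 3) and did not pass (0.13, SE 0.05, adjusted p = 0.0991), although it did in a separate fit of that line (0.00921).

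Of the 8 lists past the threshold in Huh28, all but the cell cycle list held with an estimated correlation, and another split of the same 6 arrays gave up to 7 lists with the preset correlation and 0 with an estimated one. These splits too kept part of the TGFβ difference, and 8 of 9 called the TGFβ/SMAD list with the preset correlation. The 4934 changed genes became 188 with spike-in scaling, 79.8% of them higher against 51.8%, and 41.1% were higher when the percentile was taken over bright probes. Of 115 named and called results 35 kept their call with spike-in scaling, including ID1, SMAD7, SKIL, PMEPA1, SNAI1 and all of the largest changes except MT1F (adjusted p = 0.0737). CCN2 (1.28, SE 0.33), CDH1 (0.53, SE 0.30) and CXCL8 (-0.69, SE 0.30) did not, nor did the cell cycle and biliary members, of which 0 passed. The median SE of all genes rose there from 0.0817 to 0.307, while KRT7 (0.94, SE 0.31), CCND1 (1.01, SE 0.29) and CCNA2 (0.80, SE 0.32) had larger changes than without it. MT1F also failed without control replicate 2 (0.0688) or 3 (0.0763), and its change was -1.43 without treated replicate 1 and -2.97 without treated replicate 3. Further, OSR1 failed with the value table (0.122). Normexp correction made smaller, by over 1.5 times in fold, the changes of FOXS1 (4.08), PROC (2.10), PRRX2 (1.65), TNC (1.24), KCNJ2 (-1.70), SGPP2 (-1.25, and -1.31 with a floor of 50), LRRN4CL (-1.46), OSR1 (-1.27) and KCNA4 (-1.26). The mean of its probes did so for RPRML (1.97). VIM passed with normexp correction (0.0455), with quantile normalisation (0.0261), without HuCCT1 control replicate 2 (0.0373) and without treated replicate 3 of Huh28 (0.0475).

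The signature shared by both lines comprised 1156 genes higher and 907 lower in each, against 385 and 345 for independent lists of these sizes, and 480 genes called in opposite directions against 728. Of the shared genes, 77 rose and 22 fell by at least 2-fold in each line. Among the largest mean rises were those of FOXS1 (5.19, SE 0.12), ODAPH (3.79, SE 0.04), CGB3 (3.61, SE 0.05), IL11 (3.49, SE 0.05) and CSF1R (3.16, SE 0.05). Next were NKAIN4 (2.85, SE 0.05), ANGPTL4 (2.78, SE 0.05) and IGFL3 (2.72, SE 0.10). CGB3 was well above background on 2 of 3 Huh28 controls and IGFL3 on 2 of 3 HuCCT1 controls. XYLT1 also rose in both lines, but its mean is not measured because it has only a bound in HuCCT1. The largest mean falls were in EVI2B (-2.47, SE 0.10) and EVI2A (-1.62, SE 0.04), both genes inside an intron of NF1, PPFIBP2 (-2.05, SE 0.06), TMT1A (-1.90, SE 0.06) and SGPP2 (-1.67, SE 0.08). Further mean falls were in CCN3 (-1.58, SE 0.08), the apoptosis inhibitor BIRC3 (-1.47, SE 0.03), the KIT ligand KITLG (-1.42, SE 0.06), TGFBR3 (-1.41, SE 0.08), a coreceptor for TGFβ, and PTX3 (-1.40, SE 0.04), a soluble pattern-recognition protein. Among noncoding RNAs, LINC00312 (2.20, SE 0.09), XR_109628 (2.99, SE 0.06) and TCONS_00028442 (2.26, SE 0.13, well above background on 1 of 3 control arrays in each line) rose, and PRKAG2-AS1 (-1.24, SE 0.06), XR_111781 (-1.55, SE 0.11, well above background on 1 of 3 treated Huh28 arrays) and TCONS_00026523 (-1.37, SE 0.05) fell. With normexp correction these means were nearer 0 by over 1.5 times in fold for FOXS1 (3.69), CGB3 (2.85), IGFL3 (1.92), EVI2B (-1.87), PPFIBP2 (-1.23), SGPP2 (-0.95), TGFBR3 (-0.80), TCONS_00028442 (1.05) and XR_111781 (-0.84). With a floor of 50 they were so for PPFIBP2 (-1.39), TCONS_00028442 (1.19) and XR_111781 (-0.81).

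**Figure D2:**
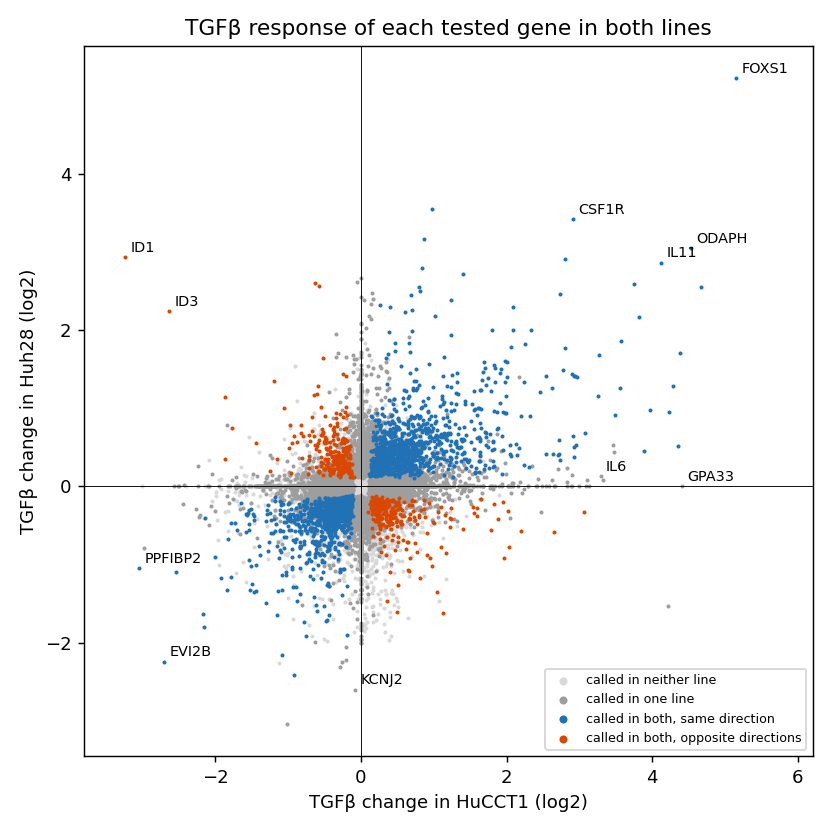
TGFβ change of each of 28094 tested genes in HuCCT1 (x axis, log2) against Huh28 (y axis, log2), coloured by whether the gene passed the threshold in neither line, in one, or in both. Genes called in both lines lie mostly in the same-direction quadrants (2063 against 480), with ID1 (-3.24 and 2.93) and ID3 (-2.64 and 2.24) far out in an opposite one; points on an axis are genes at the floor in one line.

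For the mean over both lines 4659 genes were higher and 4442 lower, and 12 lists passed. TGFβ/SMAD targets (25 of 30 higher, 0 lower, camera adjusted p = 1.15e-19), actin genes (20 of 25 higher, 1 lower, 2.46e-09) and matrix remodelling (21 of 30 higher, 5 lower, 5.39e-07) shifted upwards. So did extracellular matrix (17 of 30 higher, 4 lower, 6.66e-06), mesenchymal genes (16 of 25 higher, 3 lower, 9.60e-06), integrins (15 of 22 higher, 4 lower, 1.42e-05) and ER stress genes (12 of 20 higher, 3 lower, 0.000313). NRF2 genes (13 of 22 lower, 2 higher, 0.000148) shifted downwards. Adjusted over the list alone, the higher and lower members of these were 25 and 1, 20 and 1, 21 and 6, 18 and 4, 16 and 3, 17 and 4, 12 and 3, and 3 and 15 in the same order. Of the remaining 4, the cell cycle list (17 of 32 lower, 3 higher) had adjusted p = 0.000446 and adjusted p = 0.280 with an estimated correlation. Interferon genes (14 of 29 lower, 2 higher) had 0.000585 and adjusted p = 0.123 with an estimated correlation. Sterol genes (9 of 22 lower, 2 higher) had 0.0127 and adjusted p = 0.280 with it, and biliary genes (10 of 24 higher, 5 lower) 0.0331 and adjusted p = 0.123 with it. Adjusted over the list alone these 4 had 3 higher and 21 lower, 2 and 14, 3 and 10, and 12 and 5, and the 8 lists before them held with an estimated correlation. The biliary call ended without treated replicate 2 (0.0557) or 3 (0.0536) of HuCCT1. The other 15 lists had adjusted p between 0.0547 and 0.863. Across genes, which are not independent replicates, the changes in the lines correlated at Pearson r = 0.284 and Spearman rho = 0.272, with the same sign in 57.3%. That share is over all tested genes, including those at the floor in a line, whose change is 0. Among the 2543 genes called in both lines these values were 0.586, 0.608 and 81.1%. With spike-in scaling 605 genes passed for the mean, 85.5% of them higher against 51.2%, and 60 genes in both lines.

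Noncoding genes changed less often than the other genes, as counts with no test between the classes and no matching for signal level. In HuCCT1 613 of 5012 were higher and 492 lower, 22.0% in all against 31.2% of the other genes. In Huh28 250 were higher and 293 lower, 10.8% against 19%, and 97 rose and 86 fell in both lines. Dim genes of any class were called less often. In HuCCT1 15.6% of the dimmest of 4 level classes passed against 40.4% of the brightest, and in Huh28 9.07% against 21.8%. Whether level alone gives the lower shares of noncoding genes was not tested.

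**Figure D3:**
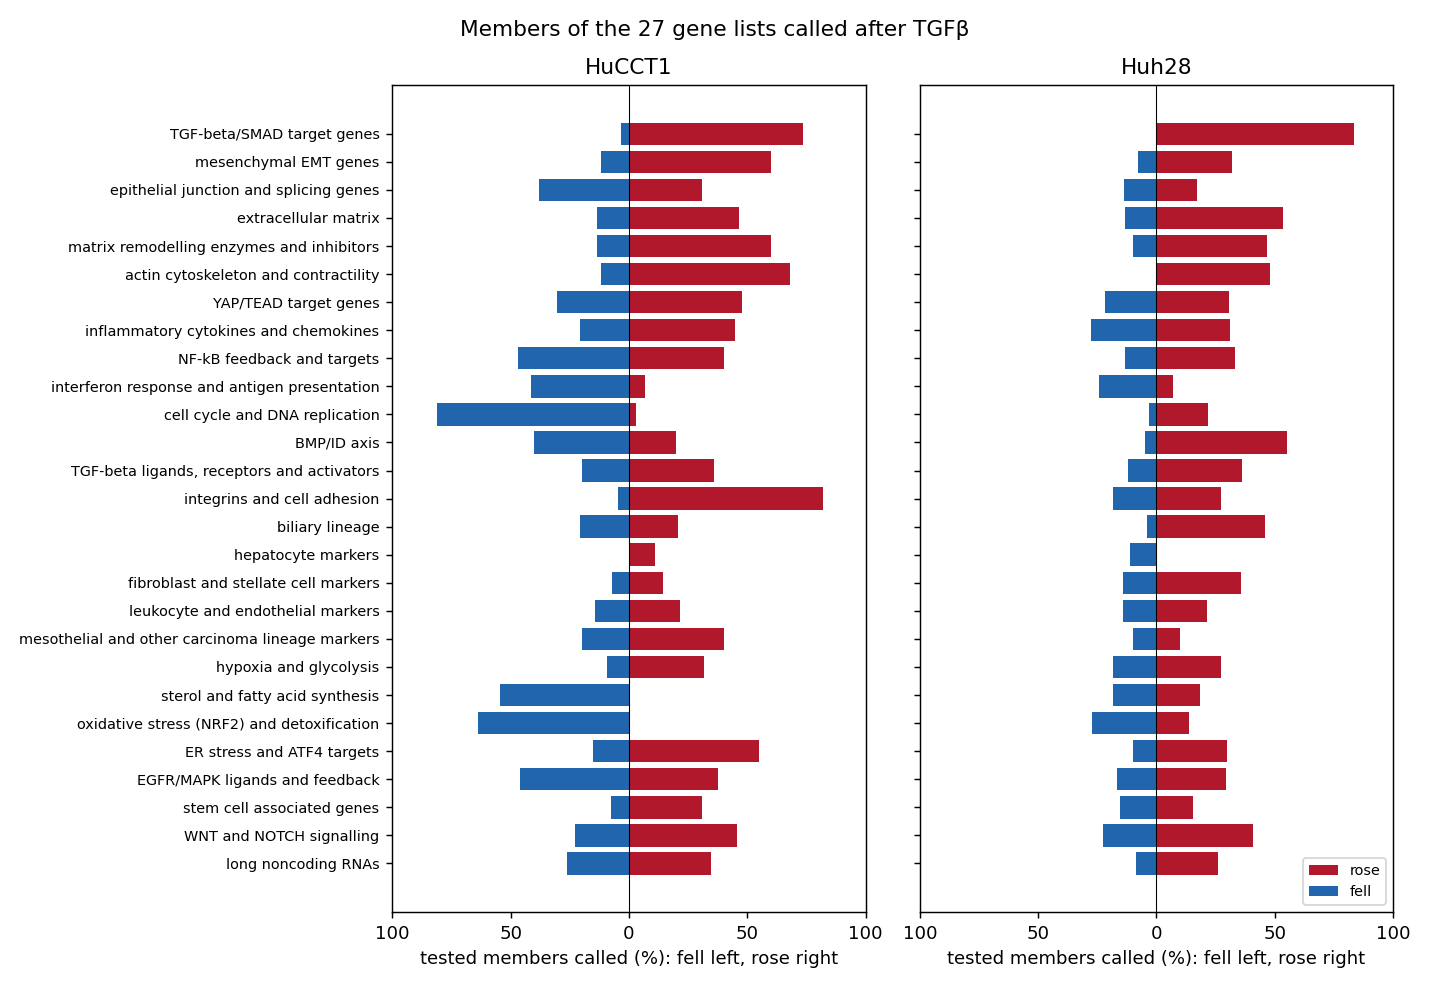
Share (%) of the tested members of each of 27 gene lists that rose (right, red) or fell (left, blue) after TGFβ in HuCCT1 and in Huh28. In the cell cycle list 26 of 32 members fell in HuCCT1 and 7 rose in Huh28, and 22 and 25 of 30 TGFβ/SMAD targets rose in HuCCT1 and Huh28.

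The TGFβ response differed between the lines in 5536 genes, 2744 with a higher and 2792 with a lower change in Huh28, by a test of the difference itself. ID1 differed by 6.17 (SE 0.07, adjusted p = 1.62e-11) and ID3 by 4.88 (SE 0.09). They were followed by PGF (3.22, SE 0.13), a placental growth factor, the MAP kinase phosphatase DUSP2 (3.15, SE 0.11) and the potassium channel subunit KCNE3 (3.00, SE 0.49). MEGF6 (2.66, SE 0.08), the claudin CLDN11 (2.55, SE 0.13) and ATOH8 (2.52, SE 0.11), a helix-loop-helix factor, came next. Lower in Huh28 were the changes of LHB (-3.83, SE 0.12), PRR5L (-3.44, SE 0.17), GPNMB (-3.39, SE 0.06), VASN (-3.24, SE 0.10), a TGFβ-binding membrane protein, and IL6 (-3.16, SE 0.07). A further 7 of the 20 largest differences had one line at the floor or not above background in controls, so that their size is not measured on both sides: RPRML (2.66), FLG (2.51), GPA33 (-4.40), XYLT1 (-3.27), SLC13A5 (-3.13), MYH16 (-3.09) and the metalloprotease MMP10 (-3.04). Of the fixed genes reported here, ZEB1 (-1.53, SE 0.11), IL11 (-1.26, SE 0.09), SNAI2 (-1.13, SE 0.13), CCN2 (-0.84, SE 0.10), CXCL8 (-0.51, SE 0.07) and VIM (-0.47, SE 0.12) had the lower change in Huh28. SKIL (-0.39, SE 0.12, adjusted p = 0.0458) passed narrowly and kept its call in 9 of 28 other settings. PMEPA1 (1.68, SE 0.07), SNAI1 (1.15, SE 0.08) and SMAD7 (0.28, SE 0.08, call kept in 19 of 28 other settings) had the higher, and CDH1 did not differ by the test (0.16, SE 0.08, adjusted p = 0.219).

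By list, the change was higher in Huh28 for 28 of 32 cell cycle genes and lower for 0 (29 and 0 adjusted over the list alone, camera adjusted p = 6e-17). It was higher for 10 of 22 NRF2 genes and lower for 0 (11 and 0 adjusted over the list alone, 2.43e-05), and for 10 of 20 BMP/ID genes and lower for 3 (10 and 3 adjusted over the list alone, 2.43e-05). It was lower in Huh28 for 12 of 22 integrins and higher for 1 (16 and 1 adjusted over the list alone, 3.68e-08). It was also lower for 18 of 30 matrix remodelling genes and higher for 7 (18 and 7 adjusted over the list alone, 2.43e-05), and for 12 of 25 mesenchymal genes and higher for 4 (14 and 4 adjusted over the list alone, 0.000466). These 6 held with an estimated correlation. The 5 other lists past the threshold did not hold with an estimated correlation. They were inflammatory genes (5 higher and 15 lower of 29, adjusted p = 0.000261, adjusted p = 0.0803 with an estimated correlation) and sterol genes (9 and 3 of 22, 0.000952, adjusted p = 0.156 with an estimated correlation). Actin genes had 4 higher and 10 lower of 25 (0.00203, adjusted p = 0.192 with an estimated correlation) and ER stress genes 2 and 9 of 20 (0.00258, adjusted p = 0.0803 with it). Biliary genes had 8 and 3 of 24 (0.0148, adjusted p = 0.0803 with it). Adjusted over the list alone, these 5 lists had 6 higher and 15 lower, 11 and 4, 4 and 14, 2 and 9, and 9 and 4. TGFβ/SMAD targets, with 8 higher and 11 lower of 30 (8 and 13 adjusted over the list alone), did not differ by the test (adjusted p = 0.0589), and the other 15 lists had adjusted p between 0.0589 and 0.993. The TGFβ/SMAD list passed with normexp correction (0.0111), with no filter on dim probes (0.0294) and with spike-in scaling (0.00671), and without treated replicate 1 of HuCCT1 (0.0487), control replicate 2 of Huh28 (0.0271) or treated replicate 3 of Huh28 (0.0427).

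With spike-in scaling the 5536 differences became 144 (29.9% higher against 49.6%), which included the 20 largest but not the other fixed genes reported here, and 0 cell cycle members. The differences that lost their call were of like size there, PMEPA1 at 1.66 (SE 0.45), ZEB1 at -1.56 (SE 0.44), IL11 at -1.29 (SE 0.42) and SNAI1 at 1.12 (SE 0.44), and the median SE of all genes rose from 0.116 to 0.434. The median difference of the cell cycle list was 0.362 against 0.391. Leaving out single arrays moved the adjusted p of SKIL, which lost its call in 10 of these 12 settings, between 0.0153 and 0.0976 and that of SMAD7 between 0.007 and 0.0601. The biliary list lost its call with normexp correction (adjusted p = 0.0946), and RPRML, FLG, GPA33, MMP10 and SKIL lost theirs with the value table (0.0858, 0.142, 0.0937, 0.231 and 0.0656), FLG also with a floor of 5 (0.196). Normexp correction made smaller, by over 1.5 times in fold, the differences of PGF (2.17), DUSP2 (2.35), KCNE3 (1.55), CLDN11 (1.32), ATOH8 (1.67), PRR5L (-2.00) and GPNMB (-2.43), and a floor of 50 those of KCNE3 (2.13), CLDN11 (1.30) and PRR5L (-2.78). Of the 7 differences not measured on both sides, all but that of MYH16 moved as much in some setting. KCNE3 and CLDN11 were well above background on 2 of 3 Huh28 controls, and PRR5L on 2 of 3 controls of each line. Splits of the arrays within each line gave up to 14 lists past the threshold, against 11 here. All other splits with as many lists kept the real HuCCT1 groups, so they held its TGFβ effect.

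Without TGFβ the lines differed in 22887 genes (81.5% of those tested), 9291 higher and 13596 lower in Huh28, with line, slide and culture medium not separable. Huh28 was higher by at least 7119-fold in CHI3L1, a secreted chitinase-like glycoprotein, at least 5617-fold in BEX1, at least 5404-fold in TENM2 and at least 1440-fold in thrombospondin THBS2, none of them well above background in HuCCT1 controls. It was also higher in the cancer-testis antigen CTAG1A (11.41, SE 0.06), TRIM58 (11.25, SE 0.11), the proteoglycan decorin DCN (10.56, SE 0.14), PTGDS (10.45, SE 0.07) and MXRA5 (10.33, SE 0.18), of which TRIM58, DCN and MXRA5 were well above background on 2 of 3 HuCCT1 controls. HuCCT1 was higher by at least 4449-fold in CST6, 2593-fold in the metalloprotease MMP7, 2351-fold in LAD1, 2271-fold in the EGFR ligand AREG, 1750-fold in F2RL1 and 1502-fold in MT1M. It was also higher in the epithelial adhesion gene EPCAM (Huh28 minus HuCCT1 -11.77, SE 0.06, well above background on 1 of 3 Huh28 controls). All 29 tested epithelial genes were lower in Huh28, CDH1 by -6.34 (SE 0.06). Of 25 mesenchymal genes 22 were higher and 3 lower, ZEB1 by 5.01 (SE 0.08), SNAI1 by 3.30 (SE 0.05) and VIM by 1.18 (SE 0.08). IL6 (6.94, SE 0.05), CXCL8 (4.05, SE 0.05), CCN2 (3.63, SE 0.07) and IL11 (1.96, SE 0.07) were higher in Huh28, and PMEPA1 (-3.89, SE 0.05) and ID1 (-3.74, SE 0.05) lower. Of 14 fibroblast markers 10 were higher in Huh28 and 2 lower, and of 32 cell cycle genes 2 were higher and 28 lower. Normexp correction made smaller, by over 1.5 times in fold, the differences of CTAG1A (10.23), TRIM58 (9.61), DCN (8.77), MXRA5 (8.82), EPCAM (-9.68), CDH1 (-5.70) and CXCL8 (3.39). The mean of its probes gave 9.01 for DCN and 6.86 for MXRA5, and quantile normalisation 1.77 for VIM. A floor of 50 gave 10.61 for TRIM58, 9.65 for DCN, 9.62 for MXRA5 and -10.47 for EPCAM, and a floor of 5 and the value table -12.50 and -12.58 for EPCAM. The differences of the genes given as bounds were below those bounds with normexp correction and with a floor of 50.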

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

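The tests of ID1 and ID3, of the dimmest genes, of the slide rows and of spike-in scaling were chosen after the results were seen. What singled out each result here is a TGFβ change that differed between HuCCT1 and Huh28 by the test of the difference itself (Huh28 minus HuCCT1, log2, limma with 3 arrays per group). This held for 5536 genes. Among 100 drawn splits of the arrays within each line only the real one gave as many, and the highest other count was 4511. A split with the labels of 1 line exchanged was not drawn, and would give the 9101 genes of the mean contrast. Such splits break up the TGFβ effect itself and do not ask whether the lines respond alike. They therefore cannot decide on chance for this number. Splits that kept the real grouping of neither line gave at most 1 gene.

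By size the differences were 6.17 for ID1, 4.88 for ID3, 3.225 for PGF, 3.15 for DUSP2, 3.00 for KCNE3, 2.665 for RPRML, 2.66 for MEGF6, 2.55 for CLDN11, 2.52 for ATOH8 and 2.51 for FLG. On the other side they were -4.40 for GPA33, -3.83 for LHB, -3.44 for PRR5L, -3.39 for GPNMB, -3.27 for XYLT1, -3.24 for VASN, -3.16 for IL6, -3.13 for SLC13A5, -3.09 for MYH16 and -3.035 for MMP10. RPRML, FLG, GPA33, XYLT1, SLC13A5, MYH16 and MMP10 were not measured above background on both sides. Among the fixed genes reported here the differences were 1.68 for PMEPA1, -1.53 for ZEB1, -1.26 for IL11, 1.15 for SNAI1, -1.13 for SNAI2, -0.84 for CCN2, -0.51 for CXCL8, -0.47 for VIM, -0.39 for SKIL and 0.28 for SMAD7.

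The gene lists that differed were cell cycle (camera adjusted p = 6e-17), integrins (3.68e-08), matrix remodelling (2.43e-05), BMP/ID (2.43e-05), NRF2 (2.43e-05), inflammatory genes (0.000261), mesenchymal genes (0.000466), sterol synthesis (0.000952), actin (0.00203), ER stress (0.00258) and biliary genes (0.0148). With an estimated correlation 5 of them lost the call, with adjusted p = 0.0803 for inflammatory, ER stress and biliary genes, 0.156 for sterol synthesis and 0.192 for actin. Of the 100 splits 11 gave as many lists, the real one included, with up to 14 against the real 11, so chance is not excluded for this number. For the mean over the lines 10 of 100 gave as many, with up to 14 against the real 12. All of those other splits kept the real HuCCT1 groups, so they held its TGFβ effect.

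ID1 and ID3 fell in HuCCT1 and rose in Huh28. An exchange of treated and control arrays in one line would turn its SMAD targets too, but in the line with fewer the TGFβ/SMAD members that rose outnumbered those that fell by 21. Scaling between arrays is argued against by the 4 changes, the smallest of which was 2.37 with spike-in scaling, beyond 2 SE (0.76), and signal near the background by 24 of 24 array values well above it. Of 6 other BMP target genes 5 (ID2, ID4, SMAD6, SMAD9 and ATOH8, not HAMP) differed between the lines in the direction of ID1. ID4 (-0.54 in HuCCT1 and 0.66 in Huh28), SMAD6 (-0.98 and 0.79) and ATOH8 (-1.77 and 0.75) moved in opposite directions. ID2 changed only in HuCCT1 (-1.65) and SMAD9 only in Huh28 (0.81). These genes were chosen after the results, ATOH8 among the largest differences, were seen. They describe a line-dependent response of BMP targets to TGFβ but are no independent test of it. Row and treatment coincide in both lines, but a row effect alike on both slides is argued against, since the changes of ID1 and ID3 differed between the slides by at least 4.88 (2 SE 0.173). A row effect on single probes that is peculiar to a slide stays open, as does which feature of the lines or of their culture media differs.

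The cell cycle list shifted downwards in HuCCT1 and upwards in Huh28 with the preset correlation. With an estimated correlation neither shift passed (adjusted p = 0.0524 and 0.365), while the difference between the lines did (0.0251). The control array that stood apart is argued against as the cause, since 25 members still fell without it, and so is signal near the background, since 32 of 32 members were well above it on all arrays. A difference in scaling between arrays cannot be told apart from a fall in HuCCT1, because the list's median with spike-in scaling was -0.153 with an SE of 0.215 for the shift itself. A shift common to all genes would not by itself give the list its place below other genes, which camera tested. Growth differences between the lines and their different culture media were not tested and stay among the open explanations.

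In HuCCT1 8301 genes changed and in Huh28 4934, of which 727 and 359 by at least 2-fold. A background difference between slide rows would act most on dim genes. At most 15.6% of the dimmest of 4 level classes passed in either line against 21.8% or more of the brightest. This cannot decide, because 2354 to 3857 tested genes per array lay at the floor, which holds down changes of dim genes. Of the calls in the dimmest class 73.9% were rises in HuCCT1 and 47.6% in Huh28, against 43.8% and 61.4% in the brightest. For the rises among dim genes in HuCCT1, 62.5% of 1059 calls were higher without control replicate 1, which leaves open how far that array made them. An effect of the row on single probes cannot be told apart from treatment, since each row held 1 treatment.

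The 10 splits of 3 against 3 arrays are too few for a share under 0.05. In HuCCT1 1 split of 10, the real one, gave 8301 genes, and the highest other gave 7, with 1105 against 4 noncoding genes and 13 against 8 lists. In Huh28 it was 1 of 10 with 4934 against 28 genes, 543 against 10 noncoding genes and 8 against 7 lists, and between the untreated lines 1 of 10 with 22887 against 2 genes. The other splits within a line kept part of the TGFβ difference, so their list counts are not free of it. For the mean over both lines (9101 against 4511) and for genes changed in both lines (2063 against 5) 1 of 100 drawn splits, the real one, gave as many. An arbitrary grouping of these arrays is thus argued against. The other splits break up any difference between treated and control arrays, whatever its source. They therefore cannot tell TGFβ from the slide row, nor show that the replicates were separate cultures.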

How the results depend on the processing

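Spike-in scaling and the floors of 5 and 50 were chosen after the data had been seen. Of 429 named results 424 were past the threshold. Of the 429, 191 kept their outcome and direction in every setting in which they were tested. These include the difference of CDH1, which was not past the threshold in any setting. The size moved by over 1.5 times in fold for 71 of the named results with normexp, for 40 with a floor of 50 and for 13 with the mean of a gene's probes, all nearer to 0. It did so for 35 with the value table (26 farther from 0) and for 30 with a floor of 5 (23 farther from 0). The cause was not tested. Leaving out single arrays gave 6860 to 8690 changed genes in HuCCT1, 4047 to 4868 in Huh28, 8122 to 9016 for the mean, 4723 to 5508 for the difference, 22230 to 22840 untreated and 1700 to 1973 in both lines. Normexp correction (6540 in HuCCT1) and the value table (7021 in HuCCT1, 4031 in Huh28, 3932 for the difference) stayed within 1.5 times of the counts reported.

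With spike-in scaling 611 genes passed in HuCCT1 (73 noncoding), 188 in Huh28 (20 noncoding), 605 for the mean, 144 for the difference, 14717 untreated and 60 in both lines. Of the first 608 and of the second 188 were among the genes called without it, in the same direction. The spike-in offsets of single arrays ranged from -0.321 to 0.278 in HuCCT1 and from -0.423 to 0.778 in Huh28, which widens the spread within groups, from a median SE of 0.0817 to 0.307 for a change within a line. A 2-fold minimum, which removes smaller changes by construction, left 727 (76 noncoding), 359 (38 noncoding), 329, 771, 11492 and 99 in the same order. An adjusted p under 0.01 left 3160 genes in Huh28, 5977 for the mean, 3379 for the difference, 1232 in both lines, and 661 and 313 noncoding genes in HuCCT1 and Huh28.

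An estimated correlation left 7 lists in HuCCT1 and 6 for the difference. Fry, which does not compare a list with other genes, called 26, 21, 25 and 25 lists in HuCCT1, Huh28, the mean and the difference for one direction, and 27 of 27 in each for either direction. List calls lost were the biliary list's difference (adjusted p = 0.0946 with normexp, 0.0655 with spike-in scaling, 0.0553 with a floor of 5, 0.0947 with a floor of 50) and the BMP/ID list in HuCCT1 (0.117 with a floor of 50). For the mean they were the sterol list (0.0782 with normexp, 0.125 with spike-in scaling) and, with spike-in scaling, the cell cycle (0.125) and biliary lists (0.0637). Those lost without single arrays or with an estimated correlation stand beside each list's result, and those lost with the replicate block are given below. List calls were gained in 15 tests with normexp, 14 with no filter on dim probes, 10 with spike-in scaling, 2 with a floor of 5 and 3 with a floor of 50.

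Direction reversed for the difference with the value table in PDGFRB (-0.788), FAP (-0.992) and TEK (-2.43), and with a floor of 5 in FAP (-0.218) and TEK (-1.02), genes near the floor in one line. It also reversed for the mean of ID1 with quantile normalisation (0.00843) and for 2 changes that had not passed, ZEB1 in Huh28 with spike-in scaling (0.0821) and SNAI2 in Huh28 without single arrays (-0.0178 to 0.101). Lists reversed only where they were not past the threshold, with these adjusted p. With normexp they were hepatocyte markers for the mean (0.89) and fibroblast markers for the difference (0.936). With spike-in scaling they were fibroblast markers in HuCCT1 (0.938) and epithelial (0.832) and stem cell genes (0.88) in Huh28. A floor of 5 turned stem cell genes in Huh28 (0.773) and fibroblast markers for the difference (0.0561), and a floor of 50 epithelial (0.963) and inflammatory genes (0.94) in Huh28 and hypoxia genes for the difference (0.93). Sterol genes in Huh28 turned with quantile normalisation (0.843), mesothelial markers in Huh28 with no filter (0.685), and inflammatory genes in Huh28 with the replicate block (0.912). Fry turned EGFR/MAPK genes in HuCCT1 (0.972) and for the mean (0.013, there past the threshold), sterol (0.988) and stem cell genes (0.947) in Huh28, BMP/ID genes for the mean (0.818) and hypoxia genes for the difference (0.924). Without single arrays the lists that turned were long noncoding RNAs (0.872 to 0.996) and biliary genes (0.711 to 0.985) in HuCCT1, hepatocyte markers for the mean (0.721 to 0.945) and hypoxia genes for the difference (0.696 to 0.994). In Huh28 they were stem cell (0.822 to 0.999), sterol (0.527 to 0.935), epithelial (0.749 to 0.935) and inflammatory genes (0.585 to 0.941). The cause was not tested for these.

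With the replicate number as a block 8583 genes passed in HuCCT1, 4853 in Huh28, 9510 for the mean, 5578 for the difference and 2027 in both lines. Same-numbered arrays correlated in their deviations at 0.0825, 0.0763 and 0.124 in HuCCT1 and 0.167, 0.0694 and 0.202 in Huh28, not all above 0.1, so the numbers were not taken as pairs, although each array correlated best with its own number, a hint from the data that is also the slide column. The block ended the calls of SKIL for the difference (0.0539), GCLC in Huh28 (0.0673), the BMP/ID list in HuCCT1 (0.091) and the biliary list for the mean (0.0577), and no other call of a named gene or list. Of the genes called without it 7560 in HuCCT1, 4264 in Huh28, 8330 for the mean and 4819 for the difference were called with it in the same direction. The untreated comparison could not be fitted with that block, nor could it, the mean or the difference with separate fits per line. Signal over background limits the fold of genes at the floor.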

Other observations

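The screen of gene families and the list of genes that moved in opposite directions were chosen after the data had been seen. Among 269 families of genes that share a symbol stem, tested with camera at the preset correlation, 21 passed in HuCCT1, 7 in Huh28 and 10 for the difference, and none with an estimated correlation (adjusted p of at least 0.446, 0.647 and 0.391). In HuCCT1 nuclear pore genes of the NUP stem fell in 14 of 22 with 0 higher (adjusted p = 0.000122) and MCM genes of the replicative helicase in 8 of 10 with 0 higher (0.000122). Mitochondrial ribosomal genes fell in 11 of 28 (MRPS, 0.000238) and 15 of 49 (MRPL, 0.00145) with 0 higher, and RAD genes in 11 of 19 with 0 higher (0.00121). Keratin genes of the KRT stem rose in 16 of 38 with 1 lower (0.000238) and SEC genes of vesicle transport in 16 of 26 with 1 lower (0.000293). Olfactory receptor genes of the OR stem rose in 21 of 128 with 0 lower (0.035). Whether signal near the background gave these rises was not tested. The CXCL chemokines fell in 5 of 9 with 0 higher in HuCCT1 (0.029) and in 5 of 9 with 1 higher in Huh28 (0.0101).

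Of the genes called in opposite directions, 414 had symbols, 61 of them changed by at least 0.5 on the log2 scale in both lines and 6 by at least 1. These 6 were ID1, ID3, CLDN11 (-1.20 in HuCCT1 and 1.35 in Huh28), the potassium channel subunit KCNE3 (-1.86 and 1.14), VSTM2L (-1.06 and 1.00) and the receptor HCAR3 (1.12 and -1.62). The rise of KCNE3 in Huh28 passed narrowly (limma, adjusted p = 0.047). KCNE3 and CLDN11 were not well above background on every Huh28 control array.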
